A study of Rattus norvegicus with 9 samples.

How the data were processed

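Bladder RNA from female rats was hybridised to 9 Agilent rat gene expression arrays with 1 colour (Cy3). The titles give 3 arrays to each of 3 groups at 3 weeks. The groups are sham operation, partial bladder outlet obstruction (pBOO), made by tying the proximal urethra over a catheter, and pBOO with tolterodine, a drug that blocks muscarinic acetylcholine receptors. The labels state that 5 specimens were examined per group and that 1 µg of RNA was labelled. They do not state whether each array carries 1 animal or a pool, so the p-values below measure the spread between these arrays. The letters that the treatment protocol uses for obstruction and sham operation are the reverse of the letters in the sample codes of the arrays titled sham and pBOO. The titles were followed, and a repeat with the names of these groups exchanged was run.

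The deposited values are spot intensities, 1 file per array. Per the file headers, the arrays were read on an Agilent scanner with Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. Per the file headers, the processed signal is an intensity that was background-subtracted and spatially detrended, and it was not normalized between arrays. The authors' raw median signal and median local background are also intensities, without normalization. The deposited quality flags (well above background, non-uniform, population outlier, saturated) are of another kind, with values 0 or 1. How the authors went on from these values to their own gene calls is not given in the sources used here. The cell culture work that the series design mentions was not used here.

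The processed signals of 42877 non-control spots were put on the log2 scale, and the 75th percentile of the non-control spots was subtracted per array, so a level of 0 is an array's 75th percentile. Spots with a non-uniformity or population outlier flag, for the spot or its background, were set to missing, and the remaining spots of a probe were averaged. Of 30367 probes, 22144 were well above background on at least 3 of the 9 arrays. Probe accessions were matched to RefSeq gene symbols of the rat assembly GRCr8, which gave 18005 probes a single symbol and left 12362 without one. The grid of the array names an older rat genome build, so no coordinates are given. A total of 13720 kept probes had a symbol, 1682 genes had more than 1 kept probe, and the probe with the highest mean over all arrays stood for its gene. A gene also needed at least 2 unflagged arrays in each group. This left 11047 genes for testing, of which 10104 had a value on every array. With flagged spots kept there were 11636 genes, so 589 genes were left out for flags alone, and their median intensity lay at percentile 70.8. Genes left out in this way include abundant products of smooth muscle (Actg2, Tagln, Des, Myl6, Tpm2, Flna), of the matrix (Col1a2, Col3a1) and of urothelium (Upk1a, Upk2, Upk3a, Krt19).

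The upper quartile of the processed signal ran from 523 to 1441 across arrays. The share of spots well above background ran from 72.1% to 80.1%, and the share of spots with a flag from 4.66% to 6.31%, with 0 saturated spots. The SD between repeated spots of a probe was between 0.0415 and 0.0685 on the log2 scale over 1390 probes spotted at least 3 times. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.171, and the median residual SD between arrays of a group was 0.214.

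Each comparison was a contrast in a single limma fit over the 9 arrays with 1 coefficient per group (R 4.3.3, limma 3.58.1, data.table version 1.17.8). The moderated test was two-sided, with 6 residual and 2.78 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all genes of a comparison with a threshold of 0.05 and no minimum fold. Values per group are means with the SD between arrays, and fold changes carry the standard error of the fit. For a gene well above background on at least 1 array of a group and on none of the other group's arrays, a lower bound on the fold is given in place of a value. It sets the mean of the first group against, on each array of the other, the higher of the gene's own level and the lowest level called well above background there. A gene well above background in neither group, or with no bound above 1, gets no fold. The fold was also left out, as said there, for some genes well above background on only 1 of 3 arrays of a group.

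Before the data were examined, 37 gene lists with 857 entries were fixed, covering pathways and cell types of the bladder wall. Of the entries, 633 were tested, 71 were too dim, 60 were lost to flagged spots, 89 had no probe with that name and 4 had no current symbol. A total of 36 lists had at least 3 tested members. The list for B and plasma cells had only 2, Pax5 and Pou2af1, and was not tested. List shifts were tested with camera in limma, two-sided, with an inter-gene correlation preset to 0.01, over genes with a value on every array, and adjusted over the lists of a comparison. Camera sets a list against all other genes, so its direction can differ from the sign of the list's median. Each list was also tested with the correlation estimated from its own genes and with fry. The estimates differed between lists, for example 0.61 for the cell cycle list and -0.011 for fibroblast markers. Some lists with an estimate below the preset 0.01, such as collagens at -0.0012, still lost calls. A larger correlation between genes therefore does not account for every call lost with an estimated correlation. In that test camera also takes the 6 residual degrees of freedom in place of a value near the number of genes. A call lost there can come from the fewer degrees of freedom, and is not by itself evidence against a list. Counts of changed members are given over all genes and adjusted over the list alone. Counts and medians cover all tested members of a list, while camera's p-value can rest on fewer. It rested on 15 of 24 urothelial, 7 of 10 collagen and 23 of 31 respiratory chain genes. The groups, the normalization, the filters, the tests, the lists, the rule for named genes and most alternatives were also fixed before the data were examined. By that rule, the named genes of a comparison were the 12 largest changes in each direction among called genes whose groups did not overlap, the 4 list members with the smallest p in each list, and a fixed set in every comparison (among them Adrb1, Adrb3, Chrm2, Chrm3, Col1a1, Col3a1, Fn1, Acta2, Tgfb1). Among named genes with several kept probes, all probes had the same sign in 26 of 28 genes for pBOO against sham, 26 of 28 for pBOO with tolterodine against pBOO and 28 of 33 for pBOO with tolterodine against sham.

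The file headers place the arrays on 3 slides. Slide 1 held sham 2, sham 3, tolterodine 1 and tolterodine 2. Slide 2 held sham 1 and the 3 arrays titled pBOO. Slide 3, scanned on the next day, held tolterodine 3. Most alternatives changed 1 choice. Normexp also replaced the processed by the median signal and added an offset, the fit with an unadjusted p also set a 2-fold threshold, and 1 fit left out 2 arrays. The alternatives were normexp background correction on the median signal with an offset of 50, quantile and array median scaling, a stricter and no filter on dim probes, flagged spots kept, the mean of probes or each probe in place of the brightest, only the compared groups, blocks for replicate number and for slide, an intensity trend with a robust prior, array weights, fold thresholds, exchanged group names, and leaving out each array. The normexp alternative, slide as a random block, the fits within slide 1 and slide 2, the relation with exchanged names and the fit without sham 1 and tolterodine 3 were chosen after seeing the data. For lists with the random block, arrays and design were whitened by the slide correlation before camera. Array weights used limma's gene-by-gene method, because its REML method did not converge. Because comparisons share arrays, their relation was set beside 100 simulated draws without group effects and without slide effects (seed 1). A further 100 draws, chosen after seeing the data, gave arrays of a slide the correlation of 0.630 that the random block estimated.

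The procedure was tested on simulated data for 10104 genes, of which 200 were changed by known folds in each comparison. For pBOO against sham it called 24% of genes changed 1.5-fold, 56% at 2-fold, 94% at 4-fold and 94% at 8-fold. For pBOO with tolterodine against pBOO the shares were 16%, 48%, 94% and 100%, and for pBOO with tolterodine against sham 32%, 72%, 88% and 96%. Of the calls, 4.83%, 5.80% and 3.85% were false in these comparisons, and a simulated list of 30 genes shifted by 0.5 was found by camera. The noise was drawn independently for each gene. These values therefore do not show how the tests behave when genes of a list are correlated, or when many genes change.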

Results

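Gene expression was measured in rat bladder RNA on 9 single-colour arrays, 3 each from rats titled sham operation, pBOO, and pBOO with tolterodine, at 3 weeks. The series title concerns how β-adrenoceptor signalling acts on matrix laid down by bladder muscle cells. Between 72.1% and 80.1% of spots were well above background, and the 75th percentile of the signal ran from 523 to 1441 intensity units. All levels below are log2 values relative to an array's 75th percentile, and changes are log2 fold changes with the standard error (SE) of the limma fit. The treatment protocol gives obstruction and sham operation letters that are the reverse of those in the sample codes. Every signed value below therefore follows the titles, and the direction of each comparison with sham or pBOO rests on them.

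Across genes, the arrays titled pBOO with tolterodine correlated more with the arrays titled sham (median Pearson r between arrays 0.957) than with the arrays titled pBOO (0.925). Arrays titled pBOO and sham had a median r of 0.933. Within groups the median r was 0.976 for sham, 0.993 for pBOO and 0.985 for tolterodine. Array sham 1 differed from sham 2 and sham 3 by more than 2-fold in 879 and 598 genes, against 122 genes between sham 2 and sham 3. It correlated at 0.966 with sham 2, at 0.976 with sham 3 and at 0.966 to 0.973 with the tolterodine arrays. For sham 2 and sham 3 the correlations with the tolterodine arrays were lower, at 0.946 to 0.962. Genes are not independent replicates, so these are descriptions of the arrays.

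The first comparison asks how the bladder with partial outlet obstruction differed from the sham-operated bladder at 3 weeks. Contractile genes of smooth muscle were higher in the arrays titled pBOO, while genes of cell division, inflammation, interferon response and urothelium were lower. With an estimated correlation between genes, where camera had 6 degrees of freedom, 0 of these list calls held. Mylk, the kinase that phosphorylates myosin light chain, stood at 0.56 ± 0.13 in pBOO and at -2.20 ± 0.08 in sham (SD, n = 3 each), a rise of 2.77 (SE 0.11; adjusted p = 2.19e-06). Il1a, an inflammatory cytokine, stood at -6.05 ± 0.42 in pBOO and at 1.95 ± 0.54 in sham (SD, n = 3 each) and fell by 8.01 (SE 0.30; adjusted p = 1.65e-06). It was well above background on 2 of the 3 pBOO arrays, where the lowest level called so lay between -6.17 and -5.84, so that fold rests on a level near background. Tk1, a thymidine kinase of dividing cells, fell by 2.31 (SE 0.21; adjusted p = 8.37e-05), from 1.1 ± 0.42 to -1.21 ± 0.08 (SD, n = 3 each). Of 11047 genes, 4695 changed, with 2295 higher and 2400 lower (3026 with normexp).

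The 24 measured genes of the contractile list had 22 that rose and 0 that fell, and the same counts adjusted over the list alone. Their median change was 1.81 (camera adjusted p = 7.8e-10; adjusted p = 0.21 with an estimated correlation) and 2.02 within slide 2. Lmod1, an actin nucleator of smooth muscle, rose by 3.38, the actin-binding Cald1 by 2.44 and the laminin receptor chain Itga7 by 2.14. Smooth muscle markers moved with them: 10 of 11 rose, all of these 11 being held by other lists too, with a median of 1.98 (camera adjusted p = 2.5e-06; adjusted p = 0.23 with an estimated correlation) and 2.19 within slide 2. Adjusted over the list alone the count was again 10. The median was 1.38 over 14 genes with flagged spots kept, and that of the contractile list 1.57 over 30. Acta2, smooth muscle actin, did not pass at 0.30 (adjusted p = 0.242), though with quantile scaling it did at 0.93. Several abundant muscle genes were left out because their spots carried flags. With flagged spots kept, Flna changed by 2.39 and Tagln by 0.77, while Actg2 at -0.44, Des at 0.24 and Myl6 at -0.48 did not pass; these genes were chosen after their values were seen.

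The cell cycle list had 27 of 30 genes that fell and 1 that rose, also when adjusted over the list alone. Its median was -1.56 (camera adjusted p = 2.1e-10; adjusted p = 0.33 with an estimated correlation) and -1.97 within slide 2. Birc5, which acts in chromosome segregation, fell by 2.62, the replication factor Cdc45 by 2.09 and the helicase subunit Mcm3 by 1.97. Of 37 cytokines and chemokines 24 fell and 2 rose (25 and 3 adjusted over the list alone). The median was -1.15 (camera adjusted p = 2.3e-08; adjusted p = 0.21 with an estimated correlation) and -1.30 within slide 2. Cxcl1, which attracts neutrophils, fell by 3.83 (SE 0.14; adjusted p = 1.65e-06) and Il1b by 3.49. Interferon response genes fell in 20 of 26 cases with 0 rising, and in 21 adjusted over the list alone. Their median was -1.25 (camera adjusted p = 7.4e-06; adjusted p = 0.43 with an estimated correlation) and -1.70 within slide 2. The antiviral GTPase gene Mx1 fell by 2.71, Ifit3 by 2.56 and the immunoproteasome subunit Psmb9 by 1.77.

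Macrophage, neutrophil and urothelial markers were lower beside these groups. Of 18 macrophage markers 11 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 5.3e-04; adjusted p = 0.24 with an estimated correlation) and -1.05 within slide 2. Tyrobp, a signalling adaptor of myeloid cells, fell by 1.47 and Aif1 by 1.32. Of 8 neutrophil markers 6 fell and 0 rose, also adjusted over the list alone, and their median was -1.38 (camera adjusted p = 5.0e-04; adjusted p = 0.24 with an estimated correlation) and -1.71 within slide 2. The calcium-binding S100a9 fell by 3.52 and S100a8 by 3.00. Among 24 urothelial genes 14 fell and 0 rose, also adjusted over the list alone, with a median of -0.85 (camera adjusted p = 0.011; adjusted p = 0.43 with an estimated correlation) and -0.76 within slide 2. Without pBOO 1 the urothelial median was -0.65 and the call was lost. The basal keratins Krt14 and Krt17 fell by 1.86 and 2.30. With flagged spots kept, Krt19 changed by -1.57, S100a6 by -0.98 and the uroplakin Upk3a by -0.64, while Upk2 at -0.11 and Upk1a at 0.00 did not pass, these genes being chosen after their values were seen.

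Matrix and stromal genes were higher in the arrays titled pBOO, and the call for collagens did not pass. Of 26 matrix glycoproteins and proteoglycans 15 rose and 1 fell, with the same counts adjusted over the list alone. Their median was 0.75 (camera adjusted p = 2.2e-04; adjusted p = 0.21 with an estimated correlation) and 0.72 within slide 2. Fbln1 rose by 2.33, Vtn, the adhesive protein vitronectin, by 3.22 and the elastic fibre protein Fbln5 by 1.74. Fn1, fibronectin, rose by 0.87 (SE 0.18; adjusted p = 0.0052), a call lost with normexp at 0.37, with flagged spots kept at 0.49 and with slide as a block at 0.52. Collagen chains had 5 of 10 that rose and 2 that fell, also adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.31), 0.42 within slide 2, and 0.30 over 12 genes with flagged spots kept. Col14a1 rose by 1.22 and Col5a3 by 1.39. Col1a1, the main chain of fibrillar collagen, did not pass at 0.11 (adjusted p = 0.509), though with quantile scaling it did at 0.74. Col3a1 was measured only with flagged spots kept and did not pass at 0.16. Matrix remodelling genes went both ways, with 10 of 33 rising and 10 falling, also adjusted over the list alone, a median of -0.01 and a mean of -0.24 (camera adjusted p = 0.81). Within slide 2 that median was 0.03. Mmp7, a protease made by epithelia, fell by 6.92, while the collagen-modifying enzyme Plod1 rose by 1.52.

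Fibroblast markers rose in 6 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 0.011; adjusted p = 0.21 with an estimated correlation) and 1.22 within slide 2. Cd34 rose by 2.11 and Gsn by 1.56. Pericyte markers rose in 5 of 8 cases and fell in 1, also adjusted over the list alone, with a median of 1.03 (camera adjusted p = 0.021; adjusted p = 0.24 with an estimated correlation) and 1.27 within slide 2. Endothelial markers rose in 5 of 12 cases with 0 falling, also adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.023; adjusted p = 0.43 with an estimated correlation). Within slide 2 the endothelial median was 0.17. The call was lost with slide as a fixed or a random block and without pBOO 1. The tight junction gene Cldn5 rose by 2.20, Mcam by 2.10 and Abcc9, a potassium channel regulator of mural cells, by 2.15.

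Among the receptor lists camera called only the muscarinic list, and single receptor genes changed in each. Adrb3, the β-adrenoceptor that relaxes detrusor muscle, rose by 2.60 (SE 0.67; adjusted p = 0.0135). Its level was -5.27 on sham 1, -2.25 on sham 2 and -2.60 on sham 3, so the size of that rise rests in part on sham 1. Adrb1 did not pass at 0.11 (adjusted p = 0.773). The β-adrenergic list had 8 of 22 genes that rose and 4 that fell, also adjusted over the list alone, a median of 0.17 (camera adjusted p = 0.36) and 0.22 within slide 2. The receptor kinase Grk2 fell by 0.73. Of 4 α-adrenoceptors 2 rose and 0 fell, also adjusted over the list alone, with a median of 1.05 (camera adjusted p = 0.31) and 0.96 within slide 2. The muscarinic list had 8 of 19 genes that rose and 1 that fell, also adjusted over the list alone. Its median was 0.64 (camera adjusted p = 0.016; adjusted p = 0.24 with an estimated correlation), equal within slide 2 at 0.64, and the call was lost with quantile scaling. Chrm3, the receptor that contracts the detrusor, rose by 2.24 (SE 0.20; adjusted p = 8.37e-05). Chrm2 rose by 0.92 (SE 0.20; adjusted p = 0.0071), a call lost with normexp at 0.12. The channel and receptor list had 10 of 28 genes that rose and 7 that fell, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.37) and 0.02 within slide 2. P2rx1, an ATP-gated channel, rose by 3.02.

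TGF-β signalling genes rose in 12 of 28 cases and fell in 6 (12 and 7 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.087) and 0.31 within slide 2. The list passed with normexp at 0.09 and without a filter on dim probes at 0.13. Ltbp1, which binds latent TGF-β, rose by 2.55, and Tgfb1 itself fell by 0.82 (SE 0.20; adjusted p = 0.0117). Growth factors rose in 8 of 23 cases and fell in 6 (10 and 6 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.36) and 0.45 within slide 2. Igf2 rose by 2.13, and the epidermal growth factor receptor ligand Areg fell by 2.15. Respiratory chain genes fell in 16 of 31 cases with 0 rising (19 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 5.1e-04; adjusted p = 0.24 with an estimated correlation) and -0.36 within slide 2. With quantile scaling that median was -0.12 and the call was lost. Cox7b fell by 1.17 and Cox5a by 0.87. Oxidative stress genes fell in 15 of 24 cases and rose in 3, also adjusted over the list alone, with a median of -0.70 (camera adjusted p = 5.3e-04; adjusted p = 0.40 with an estimated correlation) and -1.06 within slide 2. Slc7a11, the cystine transporter, fell by 3.31. Unfolded protein genes fell in 7 of 23 cases with 0 rising (6 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.034; adjusted p = 0.46 with an estimated correlation) and -0.51 within slide 2. That call was lost with quantile scaling at -0.12, with normexp and without sham 1. A list of genes reported higher in obstructed bladder, all 11 of them held by other lists too, had 1 that rose and 6 that fell (2 and 7 adjusted over the list alone). Its median was -0.66 (camera adjusted p = 0.29), -0.81 within slide 2, and -0.33 over 13 genes with flagged spots kept. Fry called the list lower. Tnc of this list, chosen after its value was seen, changed by 1.75 with those spots. Hbegf fell by 2.10 and Ccn2, a connective tissue growth factor, by 1.57.

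Among the largest falls, Duoxa2 was at least 215-fold lower in pBOO and its partner Duox2, an oxidase of epithelia that makes hydrogen peroxide, fell by 6.71. The complement gene C3 fell by 5.77, and Vnn3 was at least 68.3-fold lower. Among the largest rises, the calcium pump Atp2b4 gained 3.94 (SE 0.17; adjusted p = 2.52e-06) and Cnr1, a cannabinoid receptor, was at least 6.86-fold higher.

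Groups did not overlap for 6157 genes, 55.7% of those tested, beside 10% by chance. All arrays titled pBOO lay on slide 2 with sham 1 alone. The interferon and cell cycle means of sham 1 (0.64 and -0.58) were the highest of the sham arrays, so the medians of these lists within slide 2 are larger in size. Within that slide 2854 of 10935 genes passed, 1484 higher and 1370 lower, but the spread there comes from the pBOO arrays alone and holds none between sham arrays. With slide as a block 4813 changed, where sham 1 again stands alone for sham. The median of all genes was -0.04, which array median scaling moved to -0.11 and normexp to -0.14, and normexp lowered the share of higher calls from 48.9% to 39.0%. Of 36 lists, camera called 9 up and 9 down, and 0 held with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way, called 30.

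**Figure D1:**
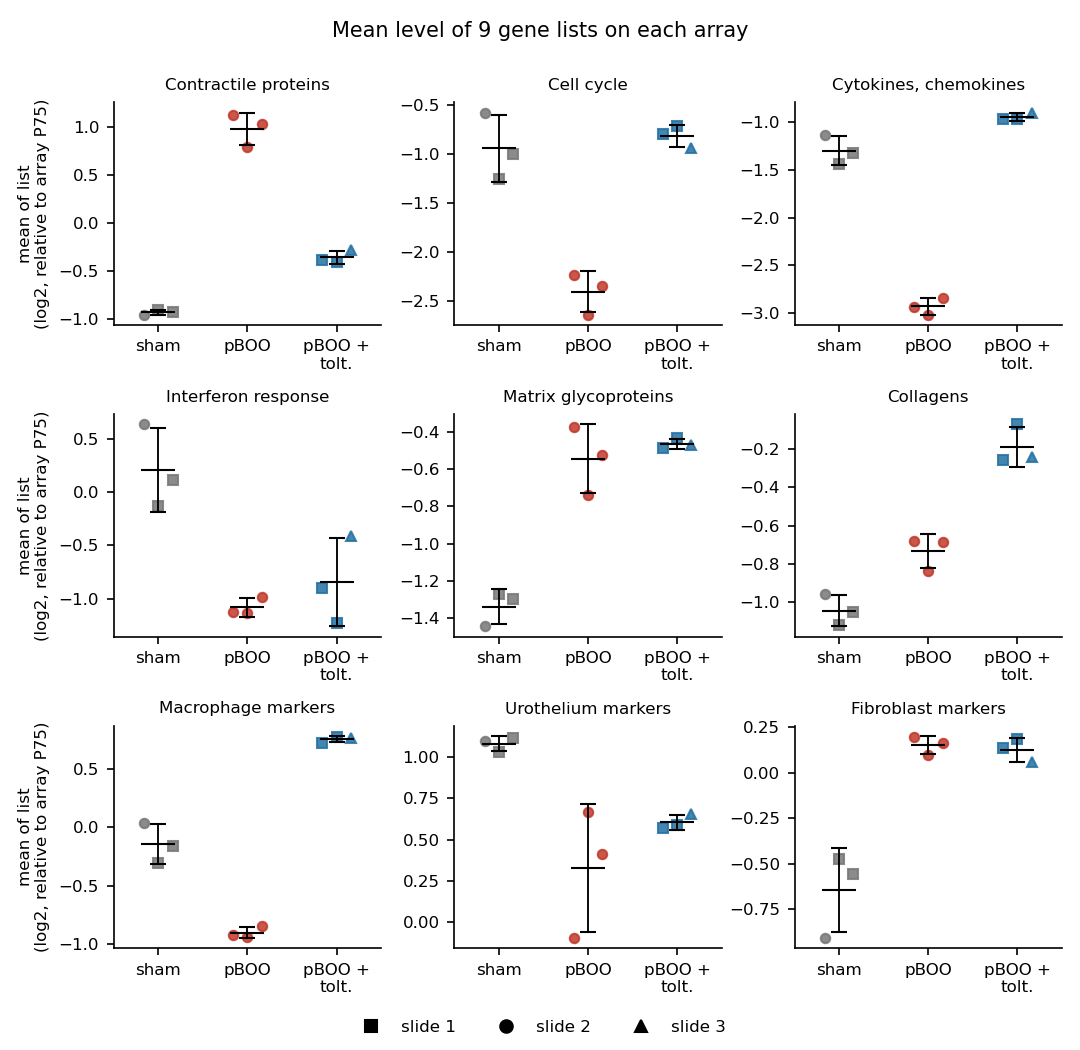
Mean log2 level of 9 gene lists on each array (y axis, relative to the array's 75th percentile), by group (x axis). Marker shape gives the slide, bars the group mean and error bars 1 SD (n = 3). The contractile list lies between 0.79 and 1.12 in the arrays titled pBOO and between -0.95 and -0.28 in all others.

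The second comparison asks what tolterodine changed in the obstructed bladder. Inflammatory, cell cycle and macrophage genes were higher in the arrays with tolterodine than in those titled pBOO, and contractile genes were lower. Again 0 of these list calls held with an estimated correlation, where camera had 6 degrees of freedom. Il1a rose by 7.51 (SE 0.30; adjusted p = 1.54e-06), from -6.05 ± 0.42 in pBOO to 1.45 ± 0.25 with tolterodine (SD, n = 3 each). C1qb, a complement component made by macrophages, rose by 2.43 (SE 0.14; adjusted p = 7.22e-06), from 2.14 ± 0.10 to 4.58 ± 0.15 (SD, n = 3 each). Mylk fell by 1.86 (SE 0.11; adjusted p = 7.78e-06), to -1.30 ± 0.06 (SD, n = 3). Of 11047 genes, 4563 changed, with 2872 higher and 1691 lower (3000 with normexp). No slide held both groups, so values with slide as a block link them through the arrays titled sham. Of these only sham 1 shared slide 2 with pBOO, so each value with the fixed block rests on that array.

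Cytokines and chemokines rose in 29 of 37 cases and fell in 4 (30 and 4 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 2.3e-09; adjusted p = 0.21 with an estimated correlation) and 1.74 with the slide block. Cxcl1 rose by 4.36 (SE 0.14; adjusted p = 1.33e-06). Macrophage markers rose in 16 of 18 cases with 0 falling (17 adjusted over the list alone), with a median of 1.86 (camera adjusted p = 1.6e-07; adjusted p = 0.21 with an estimated correlation) and 2.26 with the slide block. The scavenger receptor Cd163 rose by 2.45 and Tyrobp by 2.14. All 8 neutrophil markers rose, also adjusted over the list alone, with a median of 1.76 (camera adjusted p = 6.7e-05; adjusted p = 0.21 with an estimated correlation) and 2.39 with the slide block. S100a9 rose by 4.58 and S100a8 by 4.06. Oxidative stress genes rose in 19 of 24 cases and fell in 1 (20 and 1 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 1.4e-05; adjusted p = 0.32 with an estimated correlation) and 1.79 with the slide block. The glutathione peroxidase Gpx2 rose by 3.94 and Slc7a11 by 4.16. Interferon response genes rose in 4 of 26 cases with 0 falling (1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.75). With the slide block, which sets pBOO against sham 1 alone, that median was 0.64 and passed, and with slide as a random block it was 0.53 and did not.

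The cell cycle list had 27 of 30 genes that rose and 1 that fell, also adjusted over the list alone, with a median of 1.72 (camera adjusted p = 2.3e-09; adjusted p = 0.38 with an estimated correlation) and 2.37 with the slide block. Birc5 rose by 2.82, the spindle kinase Ttk by 2.40 and Tk1 by 2.35. Contractile genes fell in 20 of 24 cases and rose in 1, also adjusted over the list alone, with a median of -1.42 (camera adjusted p = 2.1e-08; adjusted p = 0.21 with an estimated correlation) and -1.56 with the slide block. Itga7 fell by 2.74 and Lmod1 by 2.69. Smooth muscle markers fell in 10 of 11 cases with 0 rising, also adjusted over the list alone, with a median of -1.67 (camera adjusted p = 9.2e-07; adjusted p = 0.21 with an estimated correlation) and -1.88 with the slide block. Over 14 genes with flagged spots kept the median was -1.18. Smtn, smoothelin, fell by 2.64, and Acta2 did not pass at -0.16 (adjusted p = 0.535), though with quantile scaling it did at -0.60. Pericyte markers fell in 4 of 8 cases and rose in 1 (5 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.038; adjusted p = 0.32 with an estimated correlation). The pericyte call was lost with the slide block at -0.99, with quantile scaling and without pBOO 1 or tolterodine 2. Fibroblast markers rose in 2 of 12 cases and fell in 4, also adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.47) and -0.40 with the slide block. Endothelial markers rose in 2 of 12 cases and fell in 5, also adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.15) and -0.11 with the slide block.

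Matrix remodelling genes rose in 17 of 33 cases and fell in 4 (19 and 5 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.031; adjusted p = 0.32 with an estimated correlation) and 0.62 with the slide block. Without pBOO 2 the call was lost. Mmp7 rose by 6.41, the macrophage elastase Mmp12 by 2.68 and the lysosomal protease Ctss by 2.55. Collagen chains rose in 4 of 10 cases and fell in 1 (6 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.55) and 0.45 with the slide block. Col7a1, of anchoring fibrils, rose by 2.31. Col1a1 rose by 0.56 (adjusted p = 0.0172; n = 2 with tolterodine), a call lost with quantile scaling at 0.07 and with the mean of probes at 0.02. With the slide block it was 0.59 and without tolterodine 3 it was 0.49, each from tolterodine 2 alone, as tolterodine 1 had no value. Col3a1, with flagged spots kept, did not pass at 0.28. Matrix glycoproteins rose in 8 of 26 cases and fell in 5 (8 and 8 adjusted over the list alone); their median was 0.07 and -0.18 with the slide block, while camera's direction was down (adjusted p = 0.71). Fn1 rose by 1.35 (SE 0.18; adjusted p = 5.71e-04) and the elastic fibre gene Fbn2 by 3.09. TGF-β signalling genes rose in 5 of 28 cases and fell in 8 (5 and 9 adjusted over the list alone), with a median of 0.04, a camera direction of down (adjusted p = 0.28) and 0.26 with the slide block. Ccn2 rose by 2.10 and Tgfb1 by 0.93, while Ltbp1 fell by 1.58. Genes reported higher in obstruction rose in 9 of 11 cases with 0 falling (10 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 0.0026; adjusted p = 0.32 with an estimated correlation) and 1.62 with the slide block. Of 13 genes with flagged spots kept 9 rose and 1 fell, with a median of 0.93, and Tnc, chosen after its value was seen, changed by -1.79. Hbegf rose by 3.31.

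Adrb3 fell by 3.97 (SE 0.67; adjusted p = 0.0019), to -4.75 ± 0.12 with tolterodine from -0.78 ± 0.37 in pBOO (SD, n = 3 each). Adrb1 did not pass at 0.53 (adjusted p = 0.17), though without tolterodine 3 it did at 0.88. The β-adrenergic list had 5 of 22 genes that rose and 4 that fell, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.83) and 0.23 with the slide block. Of 4 α-adrenoceptors 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.14 and a mean of -0.35, while camera's direction was up (adjusted p = 0.86). With the slide block that median was -0.02. Chrm3 fell by 1.5 (SE 0.20; adjusted p = 5.85e-04), and Chrm2 did not pass at -0.03 (adjusted p = 0.906). Muscarinic genes rose in 3 of 19 cases and fell in 8, also adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.064) and -0.33 with the slide block. The list passed without a filter on dim probes at -0.22, with the mean of probes at -0.28, with slide as a random block at -0.30 and without tolterodine 2 at -0.26. Channel and receptor genes rose in 9 of 28 cases and fell in 7 (10 and 7 adjusted over the list alone), with a median of 0.13, a camera direction of down (adjusted p = 0.75) and 0.55 with the slide block. Growth factors rose in 8 of 23 cases and fell in 6 (9 and 7 adjusted over the list alone), with a median of 0.16, a camera direction of down (adjusted p = 0.83) and 0.00 with the slide block.

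Urothelial genes rose in 14 of 24 cases and fell in 1, also adjusted over the list alone, with a median of 0.68 (camera adjusted p = 0.34) and 0.94 with the slide block. Krt17 rose by 2.71 and Krt14 by 2.60, while Krt20, a keratin of umbrella cells, fell by 4.98 (SE 0.76; adjusted p = 0.0011). With flagged spots kept, Upk2 changed by -1.0, Upk1a by -0.56, S100a6 by 0.64 and Krt19 by 1.45, while Upk3a at 0.32 did not pass, all chosen after their values were seen. Respiratory chain genes rose in 4 of 31 cases with 0 falling (2 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.83) and 0.00 with the slide block. Unfolded protein genes rose in 11 of 23 cases and fell in 1, also adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.031; adjusted p = 0.55 with an estimated correlation) and 0.84 with the slide block. That call was lost with quantile scaling. Among the largest changes, Clca4l was at least 265-fold higher with tolterodine, Duoxa2 at least 182-fold higher, and the glutathione transferase Gsta2 rose by 6.46. Stmn2, a neuronal microtubule regulator, fell by 4.87 and Ihh, a hedgehog ligand, by 4.40.

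Groups did not overlap for 6482 genes, 58.7% of those tested, beside 10% by chance. With slide as a block 4388 genes changed. With quantile scaling the median of all genes moved from 0.11 to 0.00 and the share of higher calls from 62.9% to 52.0%. Camera called 8 lists up and 4 down, of which 0 held with an estimated correlation, and fry called 25.

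**Figure D2:**
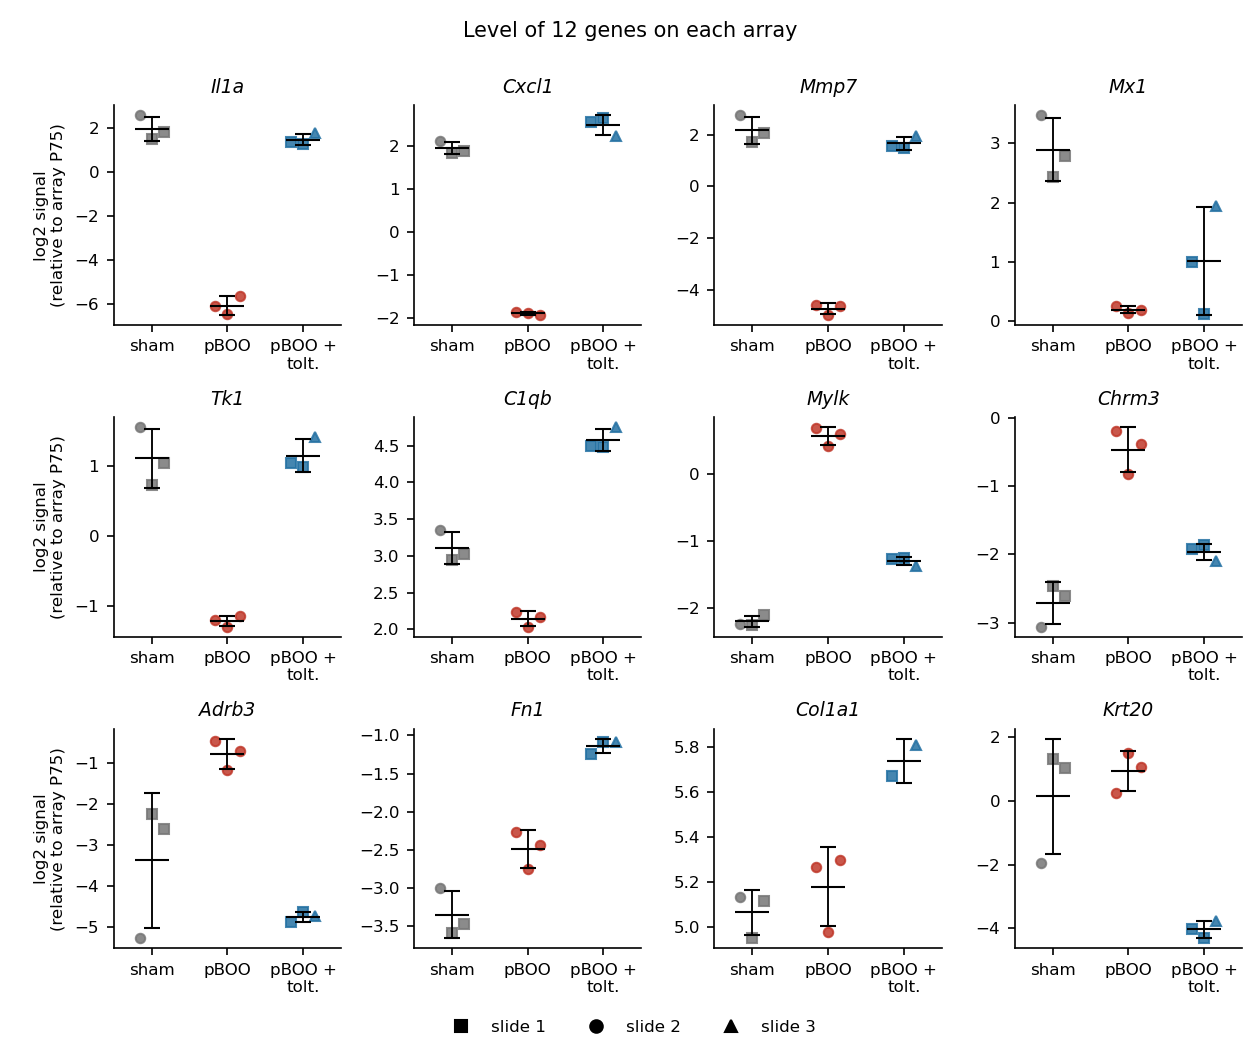
Log2 level of 12 genes on each array (y axis, relative to the array's 75th percentile), by group (x axis), with the mean and 1 SD (n = 3 unless a spot was missing). Il1a lies at -6.05 in the arrays titled pBOO on average and at 1.95 and 1.45 in those titled sham and pBOO with tolterodine.

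Both comparisons use the arrays titled pBOO, with opposite sign. Of the 4695 genes changed in pBOO against sham, 2810 changed the opposite way with tolterodine and 92 the same way. Independent lists would share 975 and 964, and arrays simulated without group or slide effects gave a mean of 9.33 opposite genes and at most 933. With arrays of a slide correlated by 0.630, as the random block estimated, the mean was 4.65 and the highest 465. The covariance of the fold changes across genes was -0.59, beside a simulated mean of -0.04 with a range from -0.21 to 0.04, and from -0.31 to 0.01 with slides correlated. Pearson r across genes was -0.74, within the simulated range from -0.95 to 0.98 (mean -0.46), and 78 of the 100 draws with slides correlated had an r as low (mean -0.82). With the names of the arrays titled sham and pBOO exchanged, the covariance was -0.17, within the simulated range from -0.22 to 0.09 but below that with slides correlated (-0.08 to 0.11). There r was -0.30 beside a simulated mean of -0.45, and 1184 genes were opposite, beside 567 for independent lists. Il1a, Cxcl1, Mmp7, C3, Tk1 and Birc5 were among the genes that fell in the first comparison and rose in the second, and Mylk, Lmod1, Itga7, Chrm3 and Adrb3 among those that rose in the first and fell in the second.

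**Figure D3:**
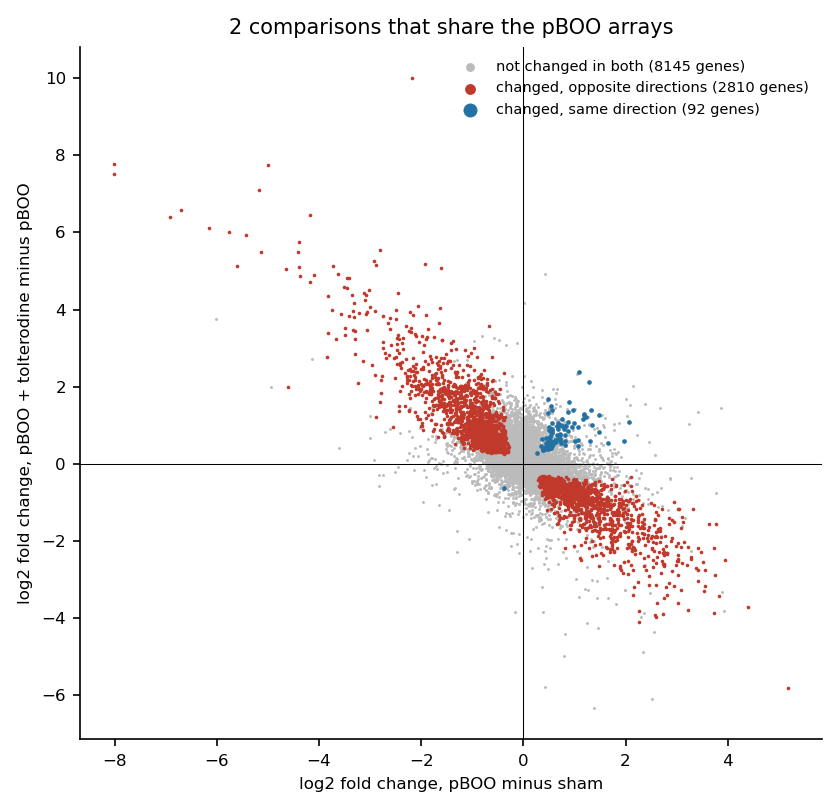
Log2 fold change with tolterodine against pBOO (y axis) over that of pBOO against sham (x axis), each point a gene. Red marks the 2810 genes changed in opposite directions, blue the 92 changed in the same direction and grey all other tested genes.

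The third comparison asks how the obstructed bladder with tolterodine differed from the sham-operated bladder. Matrix, collagen and macrophage genes were higher in the arrays with tolterodine, and interferon response and respiratory chain genes were lower. Here too 0 of these list calls held with an estimated correlation, where camera had 6 degrees of freedom. Fn1 rose by 2.21 (SE 0.18; adjusted p = 2.44e-04), from -3.35 ± 0.31 in sham to -1.14 ± 0.09 with tolterodine (SD, n = 3 each). Fbn2, a fibrillin of elastic fibres, rose by 2.75 (SE 0.19; adjusted p = 1.35e-04), from -2.37 ± 0.29 to 0.39 ± 0.24 (SD, n = 3 each). Of 11047 genes, 2695 changed, with 1968 higher and 727 lower. That count was 961 with normexp, with 656 higher and 305 lower, 1614 without sham 2, 1413 without sham 3, 1569 without tolterodine 1 and 1461 without tolterodine 2.

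Matrix glycoproteins rose in 15 of 26 cases with 0 falling (17 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 5.2e-05; adjusted p = 0.21 with an estimated correlation) and 0.81 within slide 1. The microfibril gene Mfap4 rose by 1.41 and Eln, elastin, by 1.32, a call lost for Eln with normexp at 0.52. Collagen chains rose in 9 of 10 cases with 0 falling, also adjusted over the list alone, with a median of 0.86 (camera adjusted p = 0.0047; adjusted p = 0.21 with an estimated correlation) and 0.97 within slide 1. Col6a2 rose by 1.29, Col7a1 by 1.24 and Col5a1 by 0.77. Col1a1 rose by 0.67 (adjusted p = 0.0147; n = 2 with tolterodine), a call lost with the mean of probes at 0.27. Without tolterodine 2 it was 0.74 and without tolterodine 3 it was 0.60, each from 1 tolterodine array, as tolterodine 1 had no value. With flagged spots kept Col3a1 passed at 0.44. Matrix remodelling genes rose in 16 of 33 cases and fell in 1, also adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.034; adjusted p = 0.36 with an estimated correlation) and 0.50 within slide 1. That call was lost with the slide block and without sham 1, sham 3 or tolterodine 2. The gelatinase Mmp2 rose by 1.21, the aggrecanase Adamts5 by 1.37 and the cathepsin Ctsk by 1.03. Fibroblast markers rose in 6 of 12 cases and fell in 1, also adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.016; adjusted p = 0.21 with an estimated correlation). That call was lost within slide 1 at 0.47, with the slide block and without sham 1. Fap, a serine protease of activated fibroblasts, rose by 1.81 and Pdgfra by 1.14.

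Macrophage markers rose in 14 of 18 cases with 0 falling (15 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 1.5e-05; adjusted p = 0.21 with an estimated correlation) and 1.07 within slide 1. C1qb rose by 1.47, C1qc by 1.44 and Cd163 by 1.67. Neutrophil markers rose in 4 of 8 cases with 0 falling, also adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.059), and passed within slide 1 at 0.86, with slide as a random block at 0.73, without sham 1 at 0.80 and without pBOO 3 at 0.64, but not with slide as a fixed block at 0.86. Cytokines rose in 15 of 37 cases and fell in 2 (19 and 2 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.13), and passed within slide 1 at 0.40, without sham 1 at 0.53 and without a filter on dim probes at 0.46, but not with slide as a block at 0.40. Oxidative stress genes rose in 10 of 24 cases and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.034; adjusted p = 0.58 with an estimated correlation) and 0.58 within slide 1. That call was lost without sham 2, sham 3 or tolterodine 1. Gpx3 rose by 2.03 and Gpx2 by 1.73. Interferon response genes fell in 16 of 26 cases with 0 rising (17 adjusted over the list alone), with a median of -1.0 (camera adjusted p = 4.2e-09; adjusted p = 0.47 with an estimated correlation) and -1.01 within slide 1. Usp18 fell by 2.03, Rtp4 by 1.66 and Mx2 by 1.38. Respiratory chain genes fell in 8 of 31 cases with 0 rising, also adjusted over the list alone, with a median of -0.28 (camera adjusted p = 3.8e-06; adjusted p = 0.21 with an estimated correlation) and -0.43 within slide 1. Cox7b fell by 0.65 and Ndufb9 by 0.59. Genes reported higher in obstruction rose in 6 of 11 cases with 0 falling (7 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.034; adjusted p = 0.47 with an estimated correlation) and 0.78 within slide 1. That call was lost without sham 2 at 0.61, without sham 3 at 0.53 and without tolterodine 2 at 0.59.

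Of 30 cell cycle genes 0 passed over all genes and 0 adjusted over the list alone, with a median of 0.12 and a camera direction of down (adjusted p = 0.91), and the median of 0.36 passed within slide 1 but, at the same value, not with slide as a block. Contractile genes rose in 9 of 24 cases and fell in 1 (11 and 2 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.27) and 0.31 within slide 1. Mylk rose by 0.90, a call lost with flagged spots kept at 0.32, and Itga8 by 1.48. Smooth muscle markers rose in 4 of 11 cases with 0 falling (5 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.29) and 0.23 within slide 1. Urothelial genes rose in 3 of 24 cases and fell in 4 (3 and 6 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.078) and -0.18 within slide 1. The list passed with the mean of probes at -0.19 and without sham 2 at -0.25. Krt20 fell by 4.18, with sham 1 at -1.94, sham 2 at 1.31 and sham 3 at 1.05. Endothelial markers rose in 5 of 12 cases with 0 falling (6 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.20) and 0.50 within slide 1. Pericyte markers rose in 2 of 8 cases with 0 falling, also adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.91) and -0.08 within slide 1.

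Adrb3 did not pass at -1.37 (adjusted p = 0.165), though it did with slide as a block at -2.33 and without sham 1 at -2.32, and Adrb1 did not pass at 0.64 (adjusted p = 0.135), though it did with slide as a block at 0.98 and without tolterodine 3 at 0.99. β-adrenergic genes rose in 7 of 22 cases with 0 falling, also adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.41) and 0.21 within slide 1. Of 4 α-adrenoceptors 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.10), 0.94 within slide 1 and 0.60 with normexp, where the list passed. Adra1a, which contracts the bladder outlet, rose by 1.28. Chrm2 rose by 0.88 (adjusted p = 0.0161), a call lost with normexp, quantile scaling and without tolterodine 2. Chrm3 rose by 0.75 (adjusted p = 0.0286), a call lost with normexp, quantile and array median scaling, with replicate number as a block and without sham 3, tolterodine 1 or tolterodine 2. Muscarinic genes rose in 5 of 19 cases with 0 falling (5 and 1 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.35) and 0.14 within slide 1. Channel and receptor genes rose in 8 of 28 cases and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.40) and 0.34 within slide 1. TGF-β signalling genes rose in 9 of 28 cases and fell in 4 (11 and 5 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.29) and 0.28 within slide 1. The secreted glycoprotein Fstl1 rose by 1.79, and Id1, a target of bone morphogenetic proteins, fell by 1.06. Tgfb1 did not pass at 0.12 (adjusted p = 0.714), and Acta2 did not at 0.14 (adjusted p = 0.629). Growth factors rose in 9 of 23 cases and fell in 1, also adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.29) and 0.18 within slide 1. Unfolded protein genes rose in 3 of 23 cases and fell in 1, also adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.86) and 0.29 within slide 1.

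Among the largest rises, the matrix protein Tnn was at least 11.7-fold higher. Kcnma1, a large-conductance potassium channel, rose by 4.28, but its 3 probes ranged from -0.51 to 4.28. Ihh fell by 3.58. No fold is given for Clca4l and Ghrl, which were higher, or for Ttr, which was lower, because each was well above background on only 1 of 3 arrays of the lower group. Of the genes changed against sham, 813 were higher in both the pBOO and the tolterodine arrays and 371 lower in both. Independent lists would share 409 and 158, and simulated arrays without group effects gave means of 6.43 and 6.95 and at most 640 and 632. The 371 lay below its maximum of 632, but the mean of 6.95 shows that few draws came near it. With slides correlated 0 and 0 were the most. The counts were 440 to 1168 and 80 to 641 without 1 array, and 202 and 171 with normexp. No draws were simulated for these fits, so whether the overlap exceeds a simulated maximum there was not tested. A further 313 genes changed in opposite directions, beside 579 for independent lists. Both comparisons use the same 3 sham arrays, which cannot be split into sets of at least 2.

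Groups did not overlap for 4763 genes, 43.1% of those tested, beside 10% by chance. Within slide 1, with 2 arrays a group, 5850 genes changed, 3493 higher and 2357 lower, and with slide as a block 4484. The median of all genes was 0.09 and moved to -0.05 with array median scaling, and the share of higher calls went from 73.0% to 59.6% with quantile scaling and 49.9% with array median scaling. Camera called 7 lists up and 2 down, of which 0 held with an estimated correlation, and fry called 25.

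**Figure D4:**
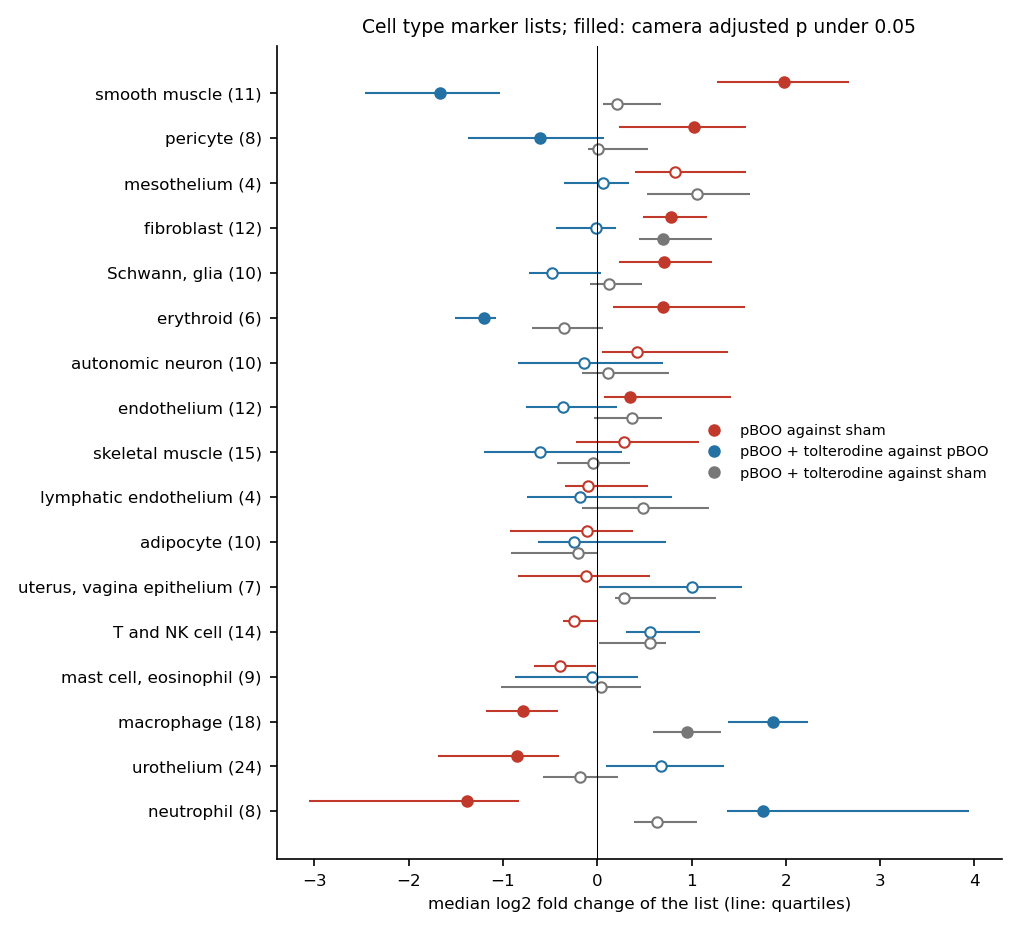
Median log2 fold change of cell type marker lists (x axis, bars from the lower to the upper quartile of the members) in the 3 comparisons. Filled points have a camera adjusted p under 0.05. Smooth muscle markers lie at 1.98 in pBOO against sham, -1.67 with tolterodine against pBOO and 0.21 with tolterodine against sham.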

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

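The tests of slide and of the share of smooth muscle below were chosen after the results were seen; the others were fixed beforehand. No result met the rules for a closer look, and groups of 3 arrays were not tested for a sample far from the others.

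In the arrays titled pBOO, contractile genes were higher and cell cycle and cytokine genes lower than in the arrays titled sham, and for these lists the arrays with tolterodine lay nearer to sham; with an estimated correlation all 3 calls were lost (camera adjusted p = 0.21, 0.33 and 0.21). A larger share of smooth muscle alone, which would lower the markers of every other cell type alike, is argued against, since the fibroblast list mean rose over the urothelial list mean by 1.55 with a pooled SD of 0.356 between arrays; a bladder sample with less urothelium and more muscle and stroma together stays open. An exchange of the names of the sham and pBOO arrays may account for the direction and cannot be told apart from the titles. The genes reported higher in obstruction had a median of -0.66 with a camera p of 0.178 (-0.33 with flagged spots kept), so neither direction passed with camera, while fry called the list lower. With tolterodine that list was higher than in pBOO (1.01, camera adjusted p = 0.0026) and than in sham (0.64, camera adjusted p = 0.034). Both calls were lost with an estimated correlation, where camera had 6 degrees of freedom. The group mean with tolterodine lay nearer to sham (1 minus r of 0.0299) than to pBOO (0.0679). These values go with an exchange, but tolterodine also sets these arrays apart, so they do not decide it. With slide as a block the contractile, cell cycle and cytokine medians passed with the preset correlation at 2.02, -1.97 and -1.26, beside 1.81, -1.56 and -1.15 over all slides, which goes against slide as the whole source, but slide cannot be told apart because this rests on sham 1, the only sham array on slide 2. An effect of obstruction, the difference the design names, stays among the open explanations, as untested.

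For each count of changed genes, the real split of the 6 arrays was 1 of the 10 splits into 3 and 3 and the only 1 with as many genes, and 10 splits cannot give a share under 0.1. The real count for pBOO against sham was 4695 and the highest of the others 1. For pBOO with tolterodine against pBOO these were 4563 and 0, and against sham 2695 and 2.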

How the results depend on the processing

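The fits with normexp, slide as a random block, a single slide, exchanged names for the relation, and without sham 1 and tolterodine 3 were chosen after seeing the data; all other alternatives were planned. The planned normexp fit on mean signals was not run, because the files hold no such column. Counts below are in the order pBOO against sham, tolterodine against pBOO, tolterodine against sham. The cause was not tested for any of these changes except where the alternative's construction shows it. Fold thresholds and single slides leave fewer genes or arrays, and exchanged names swap the comparisons.

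With normexp 3026, 3000 and 961 genes changed, with 1179, 1943 and 656 higher and 1847, 1057 and 305 lower. The planned array weights were fitted gene by gene, a method chosen because REML did not converge. They put most weight on 1 array of each group, 7.15 for sham 3, 10.1 for pBOO 3 and 4.95 for tolterodine 1, beside 0.133 for sham 1, so the counts rest on few arrays and little spread. There were 8790, 8389 and 7803, with 4367, 4523 and 4493 higher and 4423, 3866 and 3310 lower. At least 2-fold changes numbered 1736, 1814 and 1007, with 986, 1173 and 817 higher and 750, 641 and 190 lower. With an unadjusted p at that fold they were 1793, 1872 and 1090, with 1031, 1203 and 861 higher and 762, 669 and 229 lower. For tolterodine against sham, slide gave 4484 genes as a fixed block with 1731 lower, and 4266 as a random block with 1492 lower. Array median scaling gave 1459 lower. Within slide 2, where 1 sham array gives no spread between sham arrays, 2854 genes passed for pBOO against sham, 1484 higher and 1370 lower, and 2424 were called there and over all slides. Within slide 1, 5850 changed for tolterodine against sham, 3493 higher and 2357 lower, and 2613 were shared. Without sham 1 and tolterodine 3 the last comparison gave the same 4484 as the fixed block, with 1731 lower. That fit is not a separate check, because with slide as a fixed block these arrays add nothing to this comparison. Exchanged names turned 4563 into 2695 with 727 lower for tolterodine against pBOO, and 2695 into 4563 with 1691 lower against sham. Replicate number as a block gave 4344, 4231 and 2333, but residuals of equal numbers correlated by only -0.08 to 0.18. Leaving out 1 array gave 3406 to 5143, 3396 to 5336 and 1413 to 3784 genes, the last with 1239 to 2545 higher and 174 to 1239 lower.

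Lists called by camera went from 18, 12 and 9 to 0, 0 and 0 with an estimated correlation. That test also has fewer degrees of freedom, so this loss is not by itself evidence against single lists. With fry the lists called were 30, 25 and 25. The covariance of the obstruction and tolterodine changes went from -0.59 to -0.28 with normexp and -0.17 with exchanged names, where r went from -0.74 to -0.30. Opposite genes went from 2810 to 1862 and 1184. Genes higher against sham in both comparisons went from 813 to 202 with normexp and 1600 with exchanged names, and to 440 to 1168 without 1 array. Genes lower in both went from 371 to 171, to 1210, to 240 without a filter on dim probes, and to 80 to 641 without 1 array. The list reported higher in obstruction had a median of 0.64 for tolterodine against sham and 0.53 to 0.72 without 1 array.

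Directions differed for the channel and receptor list with fry (0.13) and the growth factor list with fry (0.16), tolterodine against pBOO, where fry's sign differs from camera's. Camera's direction is relative to the other genes (median of all genes 0.11) and fry's is not, so this difference lies between the tests. Camera's own direction reversed for the cell cycle list within slide 1 (0.36) against sham. Among genes, Lipe reversed with normexp (-0.042) for pBOO against sham. Bnc1 (-1.98) and Wt1 (-2.24) with the slide block and Mbp with flagged spots kept (1.02) reversed for tolterodine against pBOO, and Kcnj9 with the strict filter (0.37) against sham. Direction was compared only where either fit made a call. Fry and camera also differed in sign for lists that neither called: the β-adrenergic, matrix glycoprotein and mesothelial lists against pBOO, and the cell cycle and skeletal muscle lists against sham. Of the other list values 1855 kept their side of the threshold, 82 gained a call and 76 lost it; for named genes these were 10912, 183 and 441. Signal over background limits genes near the lowest level called well above background, which lay between -6.29 and -5.54 across arrays.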

Other observations

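The fits within slide 1 and slide 2, with normexp and with slide as a random block, and the naming of Msln and Krt19, were chosen after the results were seen; the rest was planned. Erythroid genes rose in 3 of 6 cases with 0 falling in pBOO against sham, also adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.016; adjusted p = 0.40 with an estimated correlation) and 1.05 within slide 2. With tolterodine against pBOO 5 fell and 0 rose, also adjusted over the list alone, with a median of -1.20 (camera adjusted p = 0.0025; adjusted p = 0.32 with an estimated correlation) and -1.84 with slide as a block. Alas2, the first enzyme of heme synthesis in red cells, rose by 0.92 and then fell by 1.60. Against sham, tolterodine gave 1 that rose and 2 that fell (1 and 3 adjusted over the list alone) and a median of -0.35 (camera adjusted p = 0.30), and -0.75 within slide 1. Schwann cell genes rose in 5 of 10 cases and fell in 1 in pBOO, also adjusted over the list alone, with a median of 0.71 (camera adjusted p = 0.047; adjusted p = 0.43 with an estimated correlation) and 0.96 within slide 2. Normexp, quantile scaling, the mean of probes, replicate number as a block, and leaving out sham 1, pBOO 1, tolterodine 2 or tolterodine 3 each ended that call. The neurotrophin receptor Ngfr rose by 1.90 in pBOO and fell by 1.86 with tolterodine against pBOO. In that comparison 4 Schwann genes fell and 0 rose, also adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.064), which passed without a filter on dim probes at -0.27 and without pBOO 2 at -0.50, and against sham 1 rose and 1 fell, also adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.998).

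Skeletal muscle genes rose in 6 of 15 cases and fell in 2 in pBOO against sham (6 and 3 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.12) and 0.74 within slide 2 and 0.69 with slide as a block. The last 2 values passed, but rest on sham 1, whose mean of -2.70 was the lowest of all arrays, and with slide as a random block 0.42 did not pass. The list passed without a filter on dim probes at 0.28. Casq1, calsequestrin of skeletal fibres, rose by 1.91 and the glycogen phosphorylase Pygm by 1.35. With tolterodine against pBOO 3 rose and 7 fell (3 and 8 adjusted over the list alone; median -0.61, camera adjusted p = 0.064), and against sham 1 rose and 1 fell (1 and 0 adjusted over the list alone; median -0.04, camera adjusted p = 0.50). The list passed against pBOO with normexp at -0.53, without a filter at -0.53, with replicate number as a block at -0.61, and without sham 1 at -0.61, pBOO 2 at -0.60 or tolterodine 3 at -0.71. Neuronal genes rose in 2 of 10 cases and fell in 1 in pBOO (median 0.42, camera adjusted p = 0.36), rose in 3 and fell in 3 with tolterodine against pBOO (median -0.14, camera adjusted p = 0.60), and rose in 2 with 0 falling against sham (median 0.11, camera adjusted p = 0.91), with equal counts adjusted over the list alone. The axonal growth gene Gap43 rose by 0.92 in pBOO, while Tubb3 fell by 1.90.

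T and NK cell genes had 1 of 14 that rose and 1 that fell in pBOO against sham (0 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.36). With tolterodine 6 rose and 0 fell against pBOO (7 adjusted over the list alone; median 0.56, camera adjusted p = 0.064), and 5 rose and 1 fell against sham (6 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.29). The list passed against pBOO without a filter at 0.60 and without pBOO 3 at 0.55. Cd3d, a chain of the T cell receptor complex, rose by 1.13 against pBOO and Il7r by 1.80 against sham. Mast cell and eosinophil genes had 1 of 9 that rose and 1 that fell in pBOO, also adjusted over the list alone (median -0.40, camera adjusted p = 0.74). With tolterodine 2 rose and 2 fell against pBOO, also adjusted over the list alone, where the median of -0.06 and mean of -0.22 were negative and camera's direction was up (adjusted p = 0.96). Against sham 1 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of 0.04 and a mean of -0.43 (camera adjusted p = 0.998). Lymphatic genes had 1 of 4 that rose and 0 that fell in pBOO (1 and 2 adjusted over the list alone), with a median of -0.10 and a mean of 0.29 (camera adjusted p = 0.99). With tolterodine 1 rose and 1 fell against pBOO (2 and 2 adjusted over the list alone; median -0.19, mean 0.24, camera adjusted p = 0.86), and 2 rose and 0 fell against sham (2 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.44). Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, rose by 2.11 against pBOO and 1.78 against sham. Of the B and plasma cell genes, Pou2af1 fell by 1.07 in pBOO and rose by 1.13 with tolterodine against pBOO, and Pax5 did not pass at 0.28 and -0.23.

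Hypoxia genes rose in 9 of 26 cases and fell in 2 in pBOO against sham, also adjusted over the list alone (median 0.24, camera adjusted p = 0.11), and passed with normexp at 0.10, with quantile scaling at 0.37 and without a filter on dim probes at 0.24. With tolterodine 4 rose and 4 fell against pBOO (3 and 4 adjusted over the list alone; median -0.07, camera adjusted p = 0.47), and 5 rose and 0 fell against sham (4 adjusted over the list alone; median 0.17, camera adjusted p = 0.31). Bnip3, a mitophagy receptor, rose by 1.24 in pBOO. Immediate early genes rose in 6 of 24 cases and fell in 4 in pBOO, also adjusted over the list alone (median -0.13, camera adjusted p = 0.81). With tolterodine 11 rose and 4 fell against pBOO, also adjusted over the list alone (median 0.34, camera adjusted p = 0.47), and 8 rose and 1 fell against sham (9 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 0.29). The stress-induced factor Atf3 fell by 1.52 in pBOO and rose by 1.39 with tolterodine. Genes of uterine and vaginal epithelium, tissue next to the bladder, had 1 of 7 that rose and 2 that fell in pBOO, 2 that rose with 0 falling with tolterodine against pBOO, and 2 with 0 against sham, all also adjusted over the list alone. Their medians were -0.11 (camera adjusted p = 0.81), 1.00 (0.40) and 0.29 (0.29), with -0.07 within slide 2 and 0.22 within slide 1.

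Array sham 1 stood apart from sham 2 and sham 3 in several lists. Its interferon mean was 0.64, against -0.13 and 0.11 on sham 2 and sham 3, its cell cycle mean -0.58 against -1.26 and -1.0, and its α-adrenoceptor mean -3.71 against -3.09 and -3.02. The mean of 3 mesothelial genes was -5.94 on sham 1, -2.67 on sham 2 and -3.05 on sham 3, and between -2.71 and -2.24 on the other arrays. Of 4 tested mesothelial genes 0 passed in each comparison, over all genes and adjusted over the list alone. Their medians were 0.82 in pBOO against sham (camera adjusted p = 0.36), 0.06 with a mean of -0.07 with tolterodine against pBOO (0.86), and 1.06 against sham (0.42). Within slide 2, where sham 1 is the only sham array, the median of 2.47 restates its low level. With flagged spots kept, Msln changed by -1.46 and Krt19 by -1.57 in pBOO against sham, and by 2.11 and 1.45 with tolterodine against pBOO, both chosen after their values were seen. The medians were then 0.38, 0.47 and 0.64 over 6 genes. The adipocyte mean was -2.10 on sham 1, 0.18 on sham 2 and -0.03 on sham 3. Adipocyte genes rose in 3 of 10 cases and fell in 3 in pBOO, with a median of -0.11 and a mean of -0.77 while camera's direction was up (adjusted p = 0.99). With tolterodine 0 rose and 2 fell against pBOO (median -0.24, mean 0.31, camera adjusted p = 0.41), and 0 rose and 1 fell against sham (median -0.20, camera adjusted p = 0.31), with equal counts adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, rose by 2.88 in pBOO, while Pparg fell by 0.63. Adipoq was lower too, but it was well above background on only 1 of 3 pBOO arrays, so no fold is given. With slide as a fixed block, which sets pBOO against sham 1 alone, more lists passed for tolterodine against pBOO. Their medians were -2.29 for mesothelium, -1.03 for adipocytes, -0.94 for Schwann cells and -0.71 for skeletal muscle. With slide as a random block Schwann cells at -0.80 and skeletal muscle at -0.73 passed, and mesothelium at -1.23 and adipocytes at -0.40 did not. For tolterodine against sham the adipocyte list passed within slide 1 at -0.62 and without sham 1 at -0.65, but not with slide as a fixed block at -0.62.

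Of 10104 genes with a value on every array, sham 3 lay between the other sham arrays in 71.6%, pBOO 3 between the other pBOO arrays in 70.3% and tolterodine 1 between the other tolterodine arrays in 63.2%, where 33.3% would be met if the arrays were alike. The first principal component held 54.0% of the variance and the next 25.2%.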
